A study of Mus musculus with 2 samples.

How the data were processed

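The data are RNA-seq read counts per gene from 2 stable lines of the mouse hepatocarcinoma cell line Hepa1-6, infected for 24 h with lentivirus and selected with 2 µg/ml puromycin, per the labels. One line carried the IRF8 overexpression lentivirus and the other the vector control, with 1 library in each group. Groups were taken from the lentivirus named in the labels, and the columns of the deposited table were matched to samples by name.

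The deposited values are whole-number counts per gene, with no normalization. Per the submitters' processing notes, the tools were HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the genome build mm10. Per the labels, libraries were made with the NEBNext Ultra RNA kit. The strand setting, the read length, the treatment of reads with several matches and the annotation release are not given in the sources used here. Without these, reads of overlapping genes and of near-identical copies cannot be assigned with certainty. The gene length that the deposited table lists per gene was used for the length trend only. Of 52636 gene identifiers, 52403 were found in GENCODE M21, and 49909 of those (95.24%) had the same chromosome, start and end. Coordinates are those of the deposited table.

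Library sizes were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 (0.958 for vector, 1.04 for IRF8), and CPM values, the counts per scaled library size, were computed from the deposited counts. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Protein-coding genes took 97.5% of vector counts and 97.2% of IRF8 counts, pseudogenes 1.58% and 1.92%, mitochondrial genes 2.13% and 2.21%, and ribosomal RNA 0.025% and 0.029%. Genes with a mean of at least 1 CPM were measured. With 1 library per group no test across genes was possible, so edgeR's quasi-likelihood test was not run. A size rule was used: a ratio of at least 2 or its inverse, with an exact 95% interval (Clopper-Pearson on the share of the 2 libraries' counts) that excluded 1. Levels carry exact Poisson intervals. A count of 0 was given the limit of 3 counts, 0.173 CPM in the vector library and 0.143 CPM in the IRF8 library. Intervals and limits cover counting error only, and they treat each counted read as an independent molecule. PCR copies are not independent molecules, so the intervals may be too narrow even for counting error.

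Before the data were examined, 40 gene lists were fixed. A list with at least 5 measured members was described by the percentile of its median log2 ratio among 10000 random lists, each member replaced by one of the 200 genes nearest in mean expression. It stood apart below percentile 2.5 or above 97.5. An interval of each median was made by resampling the list's members, which describes the spread between members and not between cultures. The genes named were also set by rule: the IRF family, the 12 higher and 12 lower protein-coding genes of at least 5 CPM with the interval bound farthest from no change, up to 4 members past the size rule per list, and Ccl20, Fos, Cd274, Alb, Afp, Actb and Gapdh. The rule gave 124 genes. Other list members were named after their values were seen, among them Jun, Junb and Atf4, which passed the size rule, Hsp90b1, Pdia4 and Hyou1, which did not, and genes counted at or near 0.

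The size rule was tested on simulated data drawn from the real means and library sizes. With counting error alone, 97 of 97 genes changed 4-fold and 93 of 96 changed 2.5-fold were recovered, and 22 of 12261 unchanged genes passed. With an assumed coefficient of variation of 0.2 between cultures, 98.0% and 72.7% were recovered and 342 of 12258 unchanged genes passed. Lists of 20 genes were also drawn at random from the measured genes with their real ratios. Of 40 such lists shifted down by 1 on the log2 scale, 40 stood apart, and of 40 unshifted lists 2 did. The unshifted rate follows from the random draw and does not give the rate for lists of related genes.

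The alternatives were scaling by total counts, DESeq2 1.42.0 size factors or the upper quartile, no expression filter or one at 5 CPM, fold thresholds of 1.5 and 4, a 99.9% interval, log2(CPM + 1), protein-coding genes alone, removal of a trend on expression or on gene length, and lists drawn without matching. The share of each gene's 32-base words found at another annotated locus was computed from the longest GENCODE M21 transcript of each gene. Copies in sequence without annotation were not searched, so a low share does not show that a gene is unique in the genome.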

Results

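RNA-seq counts were available for 2 stable lines of Hepa1-6, a mouse hepatocellular carcinoma cell line. One line carried a lentivirus for overexpression of IRF8, an interferon regulatory factor best known as a transcription factor of myeloid and B cells, and the other carried the vector with GFP and puromycin resistance alone. Each group had 1 library, with 18118017 counted reads for the vector line and 20042660 for the IRF8 line, and 20301 and 20723 genes had at least 1 count. Of 52636 annotated genes, 12468 were measured, meaning a mean of at least 1 CPM (counts divided by the TMM-scaled library size), and 11131 of these were protein-coding. There were no replicates, so no difference below has a replicate check or a p-value, and every interval covers counting error between these 2 libraries only. A gene is called higher or lower when its scaled CPM differed by at least 2-fold and the exact 95% counting interval of the ratio excluded 1.

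The first question was whether Irf8 itself differed between the lines. Irf8 (ENSMUSG00000041515, mm10 chromosome 8, 120736358 to 120756694, plus strand) had 1486 counts in the IRF8 library and 1010 in the vector library. These counts equal 71.1 CPM (exact Poisson 95% interval 67.5 to 74.8) and 58.2 CPM (54.6 to 61.9). The ratio was 1.22 (1.13 to 1.32), which excluded 1 but did not reach 2-fold. The annotated transcript Irf8-201 has 9 exons and 2847 bases, of which 55.3% are untranslated region, and the sequence of the transgene is not given in the sources used here. Counts on the gene as a whole cannot separate the endogenous transcript from a transgene. None of the 8 measured members of the IRF family passed the size rule. Irf1, an early target of interferon-gamma signalling, had a ratio of 1.31 (1.18 to 1.46), and Irf4, the closest relative of Irf8, had 0 counts in the vector library and 1 in the IRF8 library.

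The second question was how the transcriptome of the IRF8 line differed from that of the vector line. Stress-response and immediate-early genes were lower in the IRF8 library, led by Chac1, Atf3, Trib3 and Ddit3, while interferon-gamma-inducible GTPases such as Ifi47 and Irgm1 were higher. Guanylate-binding proteins were higher too, but Gbp4, Gbp8 and Gbp9 entered the measured set only through the IRF8 library. By the size rule 532 genes were higher (4.27% of those measured) and 454 lower (3.64%), with 365 and 396 among protein-coding genes. With scaling by total counts instead of TMM, the numbers were 684 and 351, so that 66.1% of the genes past the rule were higher, against 54.0% with TMM. With the trend on expression level removed, they were 393 and 552, or 41.6% higher. The median log2 ratio was 0.17 for the 3296 genes with 1 to 10 CPM, 0.02 for the 6673 with 10 to 100 CPM and -0.12 for the 2499 above that. The design had set random lists to be matched on expression, which limits the effect of this trend on the list comparisons.

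**Figure D1:**
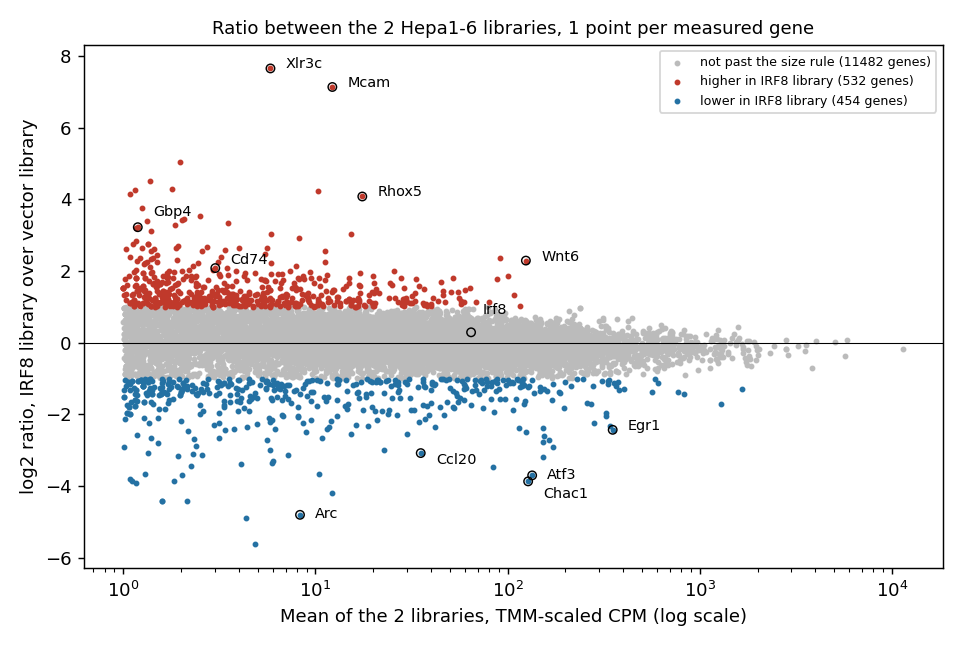
Log2 ratio of scaled CPM (IRF8 library over vector library) against the mean scaled CPM of the 2 libraries on a log axis, 1 point per measured gene. Red points are the 532 genes higher and blue points the 454 genes lower by the size rule, grey points did not pass it, and Irf8 lies among the grey points at 0.29.

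Among single protein-coding genes ranked by the interval bound nearest to no change, Mcam (melanoma cell adhesion molecule) had 509 counts in the IRF8 library and 3 in the vector library, a ratio of 141 (47.9 to 685). The X-linked homeobox gene Rhox5 was 16.9-fold higher, the amino acid transporter gene Slc38a4 8.13-fold (6.20 to 10.8) and the oncofetal glypican Gpc3 8.23-fold (5.30 to 13.4). Ptprd, a receptor tyrosine phosphatase gene, was 7.65-fold higher, the protocadherin gene Pcdhb5 6.24-fold, the growth factor gene Igf2 5.95-fold and the cytochrome P450 gene Cyp2j6 5.53-fold. Wnt6, a Wnt ligand gene, was 4.90-fold higher (4.53 to 5.30) and the actin regulator Enah 4.80-fold. Xlr3c (243 counts against 1) and Sumo2 (3207 against 522) were also among the highest, but 67.1% and 34.4% of their 32-base words occur at another locus, so their values are uncertain. On the lower side, Arc was 28.0-fold lower (15.8 to 54.8), with 12 counts in the IRF8 library and 279 in the vector library. Sprr1b, a cornified envelope precursor, was 18.5-fold lower (12.5 to 28.7), the lipase regulator Angptl8 12.7-fold (8.84 to 18.9), the tight junction gene Cldn2 10.3-fold and the retinol dehydrogenase gene Dhrs9 9.95-fold. The clock-associated repressor Ciart was 7.93-fold lower and the stress cytokine Gdf15 7.50-fold (6.97 to 8.08).

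The unfolded protein and amino acid stress response was lower as a group. Of 37 measured members, 15 were lower and 0 higher, the median log2 ratio was -0.88, and this lay below all 10000 matched random lists. Chac1, a glutathione-degrading enzyme gene, was 14.7-fold lower (13.1 to 16.4), the pseudokinase Trib3 11.1-fold (9.85 to 12.6), and Ddit3, which encodes the transcription factor CHOP, 9.21-fold (8.48 to 10.0). Ppp1r15a, a phosphatase subunit that reverses eIF2-alpha phosphorylation, was 5.21-fold lower, and Atf4, the central transcription factor of the response, 2.48-fold (2.40 to 2.57). The chaperone genes Hsp90b1, Pdia4 and Hyou1 did not pass the size rule.

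AP-1 and immediate-early genes, which are switched on rapidly by growth factors and stress, showed the same direction in each of the 32 measured members. Of these, 22 were lower and 0 higher by the size rule, and the median of -1.17 lay below all 10000 matched lists. Atf3 had a ratio of 0.0767 (0.0690 to 0.0850), IRF8 library over vector library. The phosphatase gene Dusp2 was 5.65-fold lower (5.22 to 6.11), Egr1 5.40-fold (5.16 to 5.65), Fosb 5.01-fold (4.13 to 6.11) and Fos 4.59-fold (3.63 to 5.85). Jun was 3.33-fold lower and Junb 2.72-fold. Atf3 belongs to this list and to the stress list, and it is the 1 measured gene that they share.

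Secreted signalling genes and NF-kB targets were lower on median than matched lists, with exceptions in each list. Of 15 measured chemokines, 5 were lower and 1 higher (median -0.77, below all matched lists, but at percentile 17.8 with no expression filter). Ccl20, the ligand of CCR6, was 8.48-fold lower (7.16 to 10.1), and Cxcl15, Cxcl17, Cxcl2 and Cxcl10 were the others, while Ccl9 was 4.64-fold higher (3.24 to 6.81). Of 33 cytokine and growth factor genes, 8 were lower and 5 higher (median -0.30, percentile 0.06). The epidermal growth factor family ligand Areg was 6.84-fold lower (6.35 to 7.38) and the interleukin-1 receptor antagonist Il1rn 4.06-fold, while Igf2, Inhbb, Il7, Il18 and Tnfsf15 were higher. Among 27 NF-kB targets, 3 were lower and 1, Ltb, was higher (median -0.35, percentile 0.01), and the 3 were Ccl20, Tnfaip2 and Tnip3. The bootstrap 95% interval over members included 0 for each of these medians, at -1.38 to 0.01 for chemokines, -0.51 to 0.01 for cytokines and growth factors and -0.61 to 0.24 for NF-kB targets.

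Interferon-gamma-inducible GTPases were higher. In the list of these GTPases and chemokines, 9 of 19 measured members were higher and 1 lower, and the median of 0.89 lay above all 10000 matched lists. Gbp4 was 9.34-fold higher (3.41 to 35.8), Gbp8 6.78-fold (2.90 to 19.4) and Gbp9 6.27-fold (3.12 to 14.3), each on under 10 counts in the vector library. Each lay under 1 CPM there (0.23, 0.35 and 0.52) and entered the measured set only through the IRF8 library. Their annotated spans overlap on the minus strand of chromosome 5, so their counts may not be independent. With a filter at 5 CPM the list kept 10 members and lay at percentile 98.9. Ifi47 (793 counts against 214) was 3.08-fold higher (2.64 to 3.60) and Irgm1 (875 against 304) 2.39-fold (2.10 to 2.73). The lower member was Cxcl10, at 2.11-fold (1.71 to 2.61). The type I interferon-stimulated list did not stand apart (36 measured, 5 higher, 3 lower, median 0.15, percentile 71.8), although it stood high under 3 of the alternative settings. Its higher members included Trim30a at 3.76-fold and Samd9l at 3.67-fold, and its lower members were Oasl1 at 5.89-fold, Isg20 at 2.91-fold and Usp18 at 2.14-fold. Ifit1 and Ifnb1 had 0 counts in both libraries, where the limit of 3 counts equals 0.173 CPM in the vector library and 0.143 CPM in the IRF8 library.

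**Figure D2:**
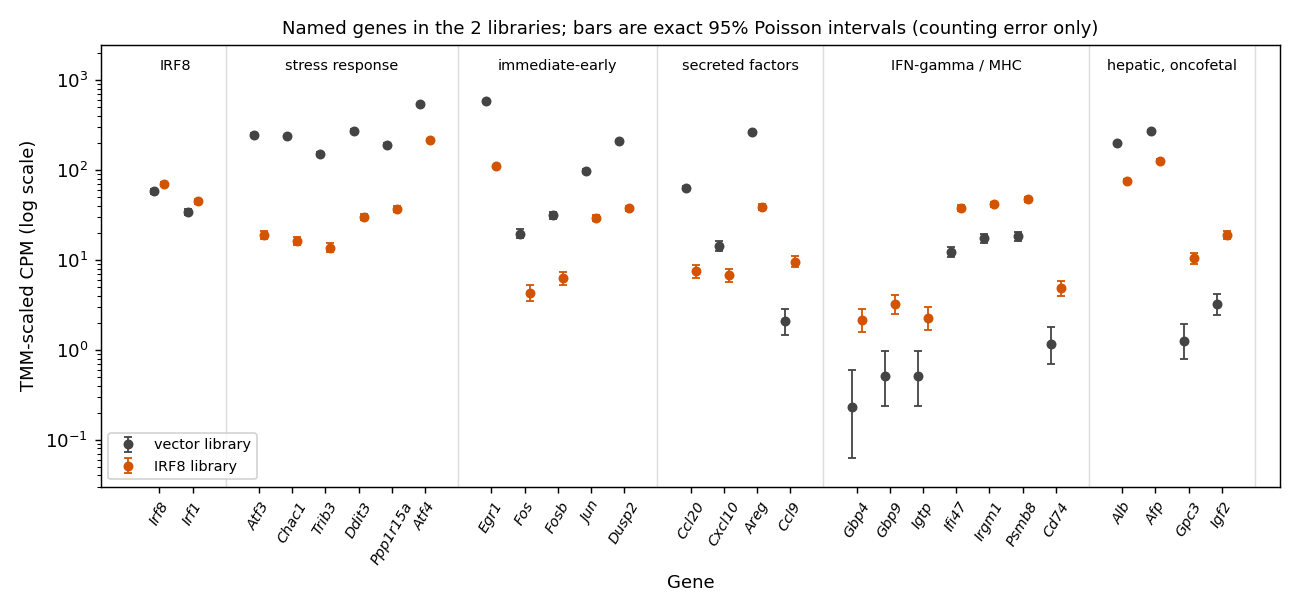
Scaled CPM (log axis) of selected named genes in the vector library (grey) and the IRF8 library (orange), with exact 95% Poisson intervals that cover counting error only. Chac1, Atf3 and Egr1 lie lower in the IRF8 library, Ifi47 and Irgm1 lie higher, and the Irf8 values of 58.2 and 71.1 CPM lie close together.

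Antigen presentation genes of MHC class I were higher on median than matched lists. Of 21 measured genes of MHC class I presentation, 1 was higher and 0 lower (median 0.39, above all matched lists), and Psmb8, an immunoproteasome subunit, was 2.59-fold higher (2.28 to 2.95). Of 9 measured genes of MHC class II presentation, 3 were higher and 1 lower (median 0.34, percentile 87.6), so this list did not stand apart. Cd74, the invariant chain, was 4.24-fold higher (2.60 to 7.22, 102 counts against 20). H2-DMb1 was 3.82-fold higher (161 against 35) and H2-Ab1 3.51-fold (55 against 13), while H2-DMa was 2.68-fold lower (18 against 40). H2-Ab1 lay at 0.75 CPM in the vector library and entered the measured set only through the IRF8 library. H2-Aa, from the same list, had 0 counts in both libraries. Ciita, the class II transactivator, had 7 counts in the vector library and 0 in the IRF8 library. Among 13 immune checkpoint genes, 1 was higher and 2 lower (percentile 47.2). The gene for PD-L1, Cd274, had a ratio of 0.758 (0.681 to 0.844), within the size rule. The poliovirus receptor Pvr and the galectin Lgals3 were 2.01-fold and 2.59-fold lower, and the ecto-nucleotidase Nt5e was 3.28-fold higher. Of 19 measured genes of innate sensing, the RNA sensors Tlr3 and Ifih1 and the peptidoglycan sensor Nod1 (70 counts against 9) were higher and 0 lower (percentile 80.7). Too few members were measured to place the NKG2D ligands (3) and lymphoid markers (2).

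Hepatocyte identity genes were lower on median. Of 26 measured members, 5 were lower and 2 higher (median -0.53, below all matched lists). Alb (albumin) was 2.66-fold lower (2.51 to 2.83), the liver transcription factor Foxa3 2.33-fold (2.13 to 2.54) and the bile acid receptor gene Nr1h4 2.20-fold, while Foxa1 was 2.41-fold higher (1.97 to 2.96). Of 13 acute-phase genes, 2 were lower and 1 higher (median -0.53, percentile 0.03, but 16.3 with no expression filter), with Cebpb, a transcription factor also counted in the stress list, 5.18-fold lower and Lbp 2.86-fold lower. Of 22 complement and coagulation genes, 2 were lower and 2 higher (median -0.35, percentile 0.16, but 10.5 with no expression filter and 3.72 for genes with under 5% shared words). The oncofetal list did not stand apart (15 measured, 3 higher, 3 lower, percentile 86.0), and its members divided: Gpc3, Igf2 and Lin28b were higher, while Afp (alpha-fetoprotein) was 2.14-fold lower (2.04 to 2.24), Sox9 3.01-fold and Tff3 2.46-fold.

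Further lists also stood apart. Autophagy and lysosome genes had a median of -0.33 (41 measured, 1 lower, 1 higher, below all matched lists), with the selective autophagy receptor gene Sqstm1 2.45-fold lower (2.41 to 2.49) and the kinase gene Ulk2 2.16-fold higher. TGF-beta pathway genes had a median of -0.26 (23 measured, 1 lower, 0 higher, percentile 1.52), and the lower gene was Id3. Replication-dependent histone genes had only 6 of 27 members measured, 5 of them lower (median -1.33, percentile 0.03). Among these was the linker histone gene Hist1h1c at 3.51-fold (3.22 to 3.83). Hist1h2bc (48 counts against 97), Hist1h4i (19 against 41) and Hist1h1d (13 against 34) were lower on few counts. Cell cycle genes had a median of 0.14 (45 measured, 2 higher, 0 lower, above all matched lists, but at percentile 96.6 among unmatched lists), and the higher genes were the centromere protein genes Cenpe and Cenpf. Housekeeping genes had a median of 0.06 (20 measured, 0 higher or lower, percentile 98.7, a standing lost in 3 alternative settings), with Actb at a ratio of 1.09 and Gapdh at 0.919. The Gapdh ratio passed 1 under scaling by total counts and with the expression trend removed. Mitochondrially encoded genes had a median of 0.12 (15 measured, 4 higher, 1 lower, percentile 98.2, a standing lost in 2 alternative settings). The higher genes, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, share at least 98.1% of their 32-base words with another locus, and their values are uncertain. Cholangiocyte markers had a median of 0.19 (11 measured, percentile 97.8) but a mean of -0.22, and Cldn4 and Sox9 were lower. This list kept its standing in only 6 of 12 alternative settings, and its median was -0.20 with no expression filter. The bootstrap intervals of the housekeeping, mitochondrial and cholangiocyte medians included 0.

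The remaining lists did not stand apart in the main setting. Among 36 genes of epithelial-mesenchymal transition and extracellular matrix, 2 were higher and 3 lower (percentile 71.1), and the matrix genes moved apart: Mmp9 (97 counts against 7) was 11.5-fold higher (5.38 to 29.4), while Mmp13 was 3.89-fold lower (3.73 to 4.06) and Ctgf 4.97-fold (4.75 to 5.20). Among 27 p53 targets, 1 was higher and 4 lower (percentile 28.4), with Gadd45a 5.86-fold lower (5.00 to 6.91) and the pro-apoptotic gene Bbc3 3.03-fold. Among 35 apoptosis regulators, Casp1 and Casp12 were higher and 0 lower (percentile 10.3, but 1.49 with chromosome medians removed). Of 27 drug and steroid metabolism genes, 2 were higher and 4 lower (percentile 37.7, but 1.93 for genes with under 5% shared words), with Cyp1a1 2.48-fold lower. Fatty acid synthesis (19 measured, 1 lower, percentile 67.6), fatty acid oxidation (21 measured, 2 lower, percentile 37.6), NRF2 targets (28 measured, 3 lower, percentile 26.1) and hypoxia and glycolysis (34 measured, 2 lower, percentile 17.0) had 0 genes higher. Among their lower genes were Dgat2, a triglyceride synthesis gene, at 5.13-fold, Acot2 at 4.62-fold, Osgin1 at 6.55-fold and Ndrg1 at 4.75-fold. These lists lay within the matched range, although hypoxia and glycolysis lay at 1.96 with chromosome medians removed. So did cholesterol biosynthesis (9.80), nuclear oxidative phosphorylation (43.9), cytosolic ribosomal proteins (12.7), Wnt targets (78.0), YAP targets (92.0) and the IRF family (10.7). Ribosomal proteins lay at 0.22 among unmatched lists, and YAP targets at 98.3 with the expression trend removed. Myc, in the Wnt list, was 2.20-fold lower (2.12 to 2.28). Myc and Ndrg1 lie on chromosome 15, whose measured protein-coding genes had a median log2 ratio of -0.31.

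Markers of other cell types gave no single direction. Of 11 measured myeloid markers, 2 were higher and 1 lower (percentile 24.6). Ptprc (CD45) had 7 counts in the vector library and 5 in the IRF8 library, and Adgre1 (F4/80) had 0 in both. Other myeloid markers were counted: Csf1r had 161 counts in the vector library and 186 in the IRF8 library, and Lyz2 had 41 and 57. Spi1, also in this list, had 17 counts in the vector library and 2 in the IRF8 library. Of 10 endothelial and stellate markers, Rgs5 and Col1a1 were higher and Vwf lower (percentile 50.4).

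**Figure D3:**
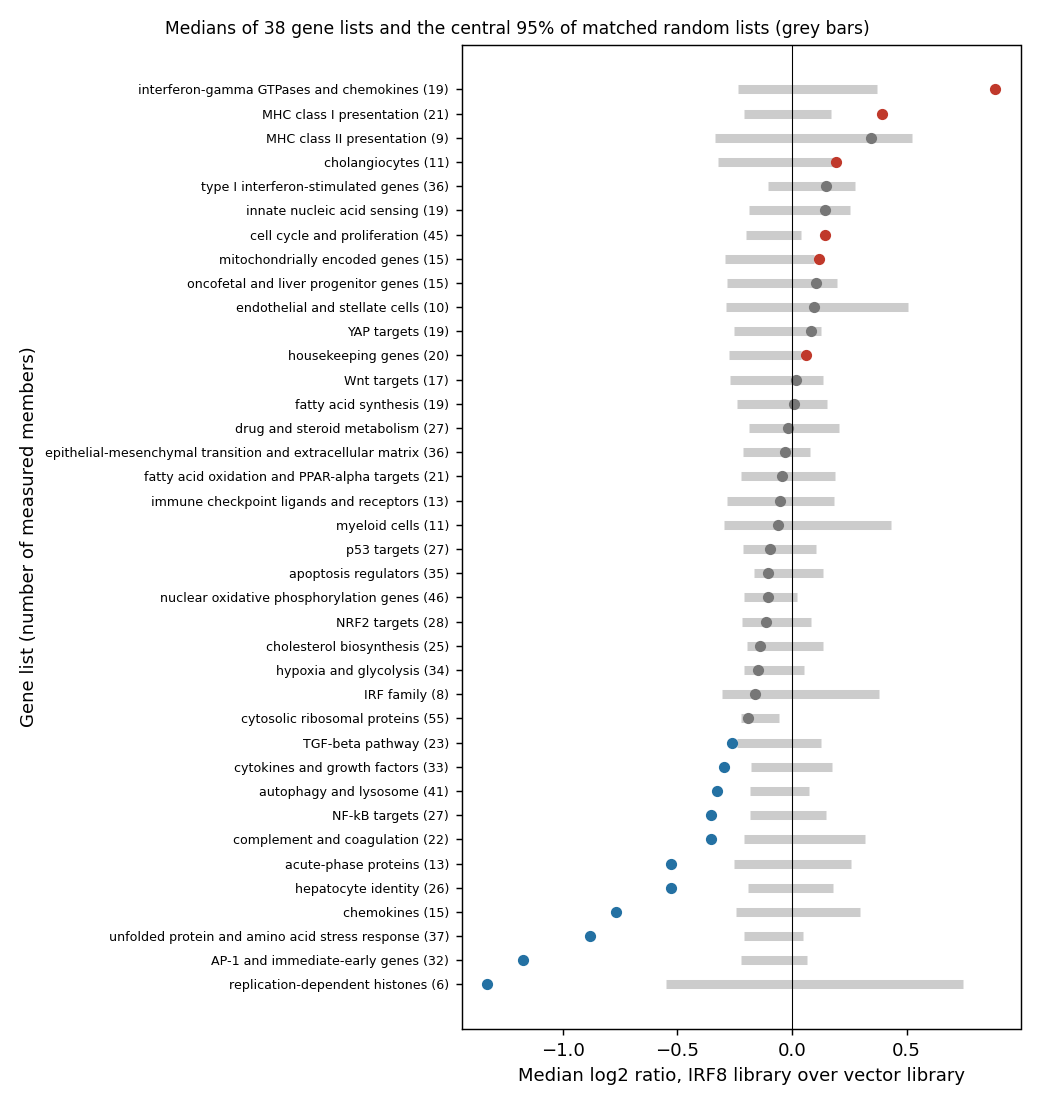
Median log2 ratio (IRF8 library over vector library) of the 38 gene lists with at least 5 measured members, with the number of measured members in brackets. Grey bars span the central 95% of 10000 random lists matched on expression, blue points mark the 11 lists below it and red points the 6 above it.

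Of the 38 lists, 11 stood apart low and 6 high, against 1.9 by chance if genes varied independently. Genes of one list do not vary independently, so chance alone gives more than that number.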

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

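Protein-coding genes with under 5% shared words, and removal of each chromosome's median, were alternatives chosen after seeing the data. The Irf8 ratio was 1.33 with scaling by total counts, which also moved the median of all genes from 0.01 to 0.13, and it stayed within its interval in the other 8 settings. The numbers of genes higher and lower were 852 and 800 with no expression filter, 221 and 266 at 5 CPM, 1302 and 1175 at 1.5-fold, 69 and 91 at 4-fold, and 275 and 300 with log2(CPM + 1), and 302 were higher with under 5% shared words. That last setting also leaves out non-coding genes, which alone gives 365 higher. The filters and these gene limits change which genes are tested, the fold thresholds change the rule, and the added 1 CPM shrinks the ratios of low genes. In the remaining settings the numbers were within 1.5 times. Gapdh turned from lower to slightly higher with total counts (0.0012) and with the expression trend removed (0.0329). The cholangiocyte median turned to -0.2002 with no filter, and the housekeeping median to -0.0321 with chromosome medians removed. The cause was not tested. The stress, immediate-early, interferon-gamma, MHC class I, hepatocyte, autophagy, NF-kB, cytokine and TGF-beta lists stood apart in all 12 settings run for lists. With no filter, chemokines (percentile 17.8), acute-phase (16.3) and complement (10.5) no longer stood apart. Cell cycle genes lay at 96.6 without matching. Type I interferon genes stood high at 5 CPM (99.4), with under 5% shared words (98.6) and with chromosome medians removed (99.95). Single settings also placed apart ribosomal proteins (0.22, low, unmatched), YAP targets (98.3, high, expression trend removed), apoptosis (1.49) and hypoxia (1.96) genes (low, chromosome medians removed) and drug metabolism genes (1.93, low, under 5% shared words). Complement genes also lost their place with under 5% shared words (3.72). Mitochondrially encoded genes lost theirs in 2 settings, housekeeping genes in 3 and cholangiocytes in 6. Of the other values of named genes, 1003 were the same and 83 moved. No paired analysis was possible because each group has 1 library. At the depth of these libraries, 3 counts equal 0.173 and 0.143 CPM.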

Other observations

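The gene families in this paragraph were chosen after seeing the data, because their members differed. Low genes can also enter the measured set through 1 library alone. The counts, medians and percentiles therefore describe the families and do not test them, and an extreme percentile follows in part from that choice. Tight junction claudins were lower: 5 of 7 measured members passed the size rule and the median log2 ratio was -1.33, with Cldn4 at 916 counts in the IRF8 library against 4614 in the vector library. Genes of squamous differentiation, which build the cornified envelope of keratinocytes, had 11 of 17 members lower and 2 higher (median -1.31), among them Krt76 (3 counts against 53) and S100a7a (18 against 95). Circadian clock genes had 6 of 16 members lower and 1 higher (median -0.55), with Per1 (527 against 999), Nr1d1 (328 against 676) and Nfil3 (217 against 660) lower and Per3 (69 against 26) higher. The cytosolic aminoacyl-tRNA synthetases Cars, Aars and Wars were lower among 20 measured (median -0.30, percentile 1.28). Among the beta protocadherins, which are cell adhesion proteins, Pcdhb16 (208 counts against 71) and Pcdhb17 (91 against 36) were higher, while Pcdhb19 (46 against 2) and Pcdhb14 (33 against 8) were measured only through the IRF8 library. Of 271 zinc finger genes named Zfp, 27 were higher and 4 lower, against means of 19.2 and 12.8 in matched random lists (median 0.20, percentile 99.99).

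Of the tests that follow, those on culture state, Irf8, type I interferon, chromosomes 15 and 16 together, chromosome 16 alone and chromosome 15 alone were chosen only after the result was seen.

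The stress and immediate-early lists together had 68 measured members, 36 lower and 0 higher, with a median of -1.08. Removing a trend on gene length left the median at -1.02, and removing a trend on GC content left it at -1.01, so neither trend accounts for the pattern. Immediate-early genes respond quickly to handling and medium change and the stress genes to nutrient supply, so a different state of the cultures at harvest may be the source. With 1 library per group this cannot be told apart from an effect of IRF8. No biological explanation is established.

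Processed pseudogenes were higher: of 592 measured, 112 were higher and 13 lower, with a median of 0.33 against 0.09 in matched protein-coding genes. Their median lay above all matched lists (percentile 100), which argues against a trend with expression level. The pattern was not limited to processed copies, because unprocessed pseudogenes stood high too (n = 53, 13 higher, 0 lower, median 0.34, percentile 98.93). Protein-coding genes with at least 50% shared words also stood high (n = 233, median 0.08, percentile 99.37), and mitochondrial protein genes with at least 90% shared words had a median of 1.59 (n = 5) against -0.08 in the others (n = 8), consistent with more reads placed on near-identical copies in the IRF8 library, although coding genes with 5 to 25% and 25 to 50% shared words had medians of -0.03 and -0.07 and did not follow. Counts over 1688 olfactory and vomeronasal receptor genes, which these cells are not thought to express, were 1.37 times higher (1.22 to 1.54), while lincRNA and antisense genes ran the other way (n = 251, 13 higher, 25 lower, median 0.02 against 0.13 in matched coding genes, percentile 2.22). Whether genomic DNA contributed remains open, and no biological explanation was tested.

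Irf8 was higher in the IRF8 library by a ratio of 1.22. Exchanged labels are not excluded by this ratio, because the spread of Irf8 between cultures is unknown with 1 library per group. A transgene of another species or with altered codons may add few reads to mouse Irf8, whereas a mouse coding sequence would be counted there over 1272 of the 2847 bases of Irf8-201. The gene length of Irf8 given with the counts was longer, at 7055 bases. With 0 libraries for which reads or counts per exon were analysed here, how far a transgene was counted remains open. Directions in the whole text therefore rest on the labels.

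One hypothesis was that the higher interferon-gamma GTPases reflect an ongoing type I interferon response. The type I list lay at percentile 71.77 with a median of 0.15, against 0.89 for the GTPase list, and Oasl1, Isg20 and Usp18 were lower, but it stood high in 3 alternative settings (99.36, 98.6 and 99.95), so the hypothesis remains open.

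Another hypothesis concerned chromosome copy number. It was first written for genes near 0 in one library, such as Mcam, as a chromosome median more than 0.3 from that of all measured genes. The largest deviation was 0.3568, on chromosome 16, which passes that bound, but the bound was set too low to bear on such genes, since a shift of this size cannot take a gene to near 0. It was then written for chromosomes 15 and 16 together, picked because their medians were seen to be the lowest (-0.3222 and -0.3568). Each was cut into 3 parts with near-equal numbers of measured protein-coding genes, not into parts of equal length. The prediction was a median below -0.2 in each part of both, and it failed, because the highest part lay at -0.0952. The 2 chromosomes were separated only after that. The 3 parts of chromosome 16 then lay at -0.32, -0.38 and -0.40 relative to all measured genes, the highest at -0.3218, which may reflect a different copy number of chromosome 16 in the 2 lines. This split was chosen from the values it describes. On chromosome 15 the parts lay at -0.23, -0.65 and -0.10, and the bootstrap intervals of the highest and the lowest were 0.454 apart, which argues against a shift of the whole chromosome. The middle part spans 75216376 to 85062828 (mm10), and 145 of its 153 measured protein-coding genes (94.8%) lay below the median of all genes.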
